A study of Mus musculus with 16 samples.

How the data were processed

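Total RNA (100 ng per sample) from the heart apex of 16 mice was labelled with 1 dye and hybridised to Agilent mouse arrays, with 4 mice in each of the groups control, AKT1 KO, AKT2 KO and AKT1+AKT2 DKO. Per the file headers, the scanner files were made with Agilent Feature Extraction 12.0.3.1 and hold the intensity of each spot, with its background already subtracted by the software, and flags for spots that are saturated, uneven or well above background. The values in the deposited table are log2 values that the authors normalized between arrays and centred on each probe's median over the 16 samples. Each array has there the same mean (0.0566), and its correlation with quantile-normalized intensity values was 0.9911 to 0.9995. Groups were taken from the sample labels, 0 sample columns were left unused, and the slide and the position on it were read from the file headers. The 2 slides carried 8 arrays each in 2 rows and 4 columns, and each group always lay in 1 column.

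The main values were log2 of the background-subtracted intensity minus the 75th percentile of the array. The 59305 spots that are not controls carried 56605 distinct probes, of which 32994 (58.3%) had a gene symbol, for 22911 symbols. The 75th percentile of the intensity ranged from 492.1 to 809.4 over the arrays, and 43.11% to 54% of the probes lay well above background. A probe was kept when it lay well above background on all 4 arrays of at least 1 group, and 118 probes with outlier flags were dropped. Of the 19340 kept probes with a symbol the brightest per symbol was used, which left 13725 genes, 4558 of them with more than 1 kept probe. The 23611 probes without a symbol were left out of the gene tests, and 7056 of them past the filter were tested apart. Chromosomes and distances between genes came from the GRCm38.p6 reference and the file annotation. The position of each probe within its transcript was not available.

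Groups were compared with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) for reading. A linear model with 1 mean per group was fitted to all 16 arrays (12 residual degrees of freedom, 2.54 prior degrees of freedom), and moderated tests were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. The 7 comparisons were the 3 knockouts against control, the 3 pairs of knockouts, and the departure from additivity, which is DKO minus AKT1 KO minus AKT2 KO plus control. Single Akt values were also tested by exact permutation over the 16 swaps within 4 pairs of arrays. Where a gene was below background on all arrays of 1 group, a lower bound of the fold change was computed with those arrays raised to their lowest signal well above background. It holds on the scale of the main values, since the offset of normexp shrinks the changes of dim probes.

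The 36 gene lists covered signalling, cardiomyocyte function, metabolism, matrix and inflammation, stress, and markers of other cell types. They were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over 144 tests (36 lists in 4 comparisons). Camera with an estimated correlation and fry were the alternatives. Single members of a list were counted by the adjustment over all genes and by a count adjusted over the list alone, and where a single count is given both were equal. Calls near Akt1 and Akt2 were tested by a one-sided Fisher exact test within 10 Mb. The overlap of comparisons was set against 100 simulations of unchanged groups that share the real number of control arrays, and against fits with 2 separate control arrays for each comparison.

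The genes named were Akt1 and Akt2, the 10 largest rises and 10 largest falls among called genes whose 4 knockout arrays all lay on 1 side of all 4 control arrays, and up to 4 called members with the smallest adjusted p of each list. In the comparisons between knockouts and for additivity the 5 largest called changes each way were named. Genes without a proper name were passed over, and 3 genes that the rule names are not reported here. The tests, lists, naming rule and first set of alternatives were chosen before the data were examined.

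Those alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median of detected probes, the authors' values, no filter or a stricter filter on dim probes, the mean of a gene's probes, array quality weights, a trended and robust prior, only the groups compared in the fit, blocks for slide, slide and row or replicate number, and leaving out each array in turn. Normexp used the median pixel intensity of the spot, since the files hold no mean. Chosen after seeing the data were fits within each slide, without the 4 arrays of row 2 of slide 2, without genes of chromosomes 7, 8 and 12, list values under each scaling, within each slide and without AKT1 KO replicate 1 or DKO replicate 3, and counts per chromosome with random draws of neighbours.

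Each slide and row held 1 array of each group. Deviations from the group means of arrays at the same slide and row correlated above 0.1 in all 4 pairs of control with AKT1 KO (0.13 to 0.38), AKT2 KO (0.141 to 0.365) and DKO arrays (0.14 to 0.316), so these were taken as paired by slide and row. The pairs of knockouts were not, with at least 1 value under 0.1 each. Replicate numbers followed slide and row in the control, AKT2 KO and DKO arrays and in 1 of 4 AKT1 KO arrays. Camera with these blocks was added after the results were seen.

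Limma ran on simulations with real means but equal group spread, unlike the data. In the simulated DKO comparison 55.2% of 67 genes changed by 0.5 log2 units were recovered, 85.1% of 67 changed by 1 and 100% of 66 changed by 2, with 15 calls among 13525 unchanged genes. With no change put in, limma called 0 of 13725 genes for AKT1 KO.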

Results

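RNA from the heart apex of 16 male mice aged 3 months was measured on 1-colour Agilent mouse arrays, with 1 array per mouse. The mice formed 4 groups of 4: a control group and groups labelled AKT1 KO, AKT2 KO and AKT1+AKT2 DKO, the last with both genes targeted. AKT1 and AKT2 are kinases that act downstream of the insulin receptor and of growth factor receptors. Per the descriptions the knockouts were made in adult cardiomyocytes with MerCreMer, a Cre recombinase fused to a hormone receptor domain that hydroxytamoxifen switches on. By the same descriptions control mice carried MerCreMer without floxed alleles, all mice received 500 µg of hydroxytamoxifen a day for 5 days, and hearts were taken 21 days after induction. The titles of all 16 samples nonetheless read "untreated", while their labels name tamoxifen and no further treatment. The arrays held 56605 distinct probes, of which 24400 to 30565 per array lay well above background, and 13725 genes were tested. The number of arrays limits the precision of every value.

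The median standard deviation of a gene within a group was 0.090 log2 units in control hearts, 0.162 in AKT1 KO, 0.114 in AKT2 KO and 0.248 in DKO hearts (n = 4 each). DKO replicate 3 stood apart from the other DKO arrays, with a score of 78.6 on the first principal component against 42.5 to 47.8. Each of the 2 slides held 2 arrays of each group. Within a slide every group kept its own array column, so that an effect of the column cannot be separated from the group.

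The first question was whether the targeted transcripts were lower in the hearts labelled as knockouts. Akt2 (NM_001110208, chromosome 7 of GRCm38.p6) fell from 4.91 ± 0.062 log2 units in control hearts to 2.54 ± 0.092 in AKT2 KO and 2.91 ± 0.10 in DKO hearts (SD, n = 4 each). These falls were 5.17-fold and 4.01-fold, with log2 changes of -2.37 and -2.0 (SE 0.089 each, limma adjusted p = 1.39e-09 and 1.54e-09). The other 2 Akt2 probes had log2 changes of -2.61 and -1.09 in AKT2 KO and of -2.27 and -1.15 in DKO hearts. Akt2 was 4.78 ± 0.178 in AKT1 KO hearts (SD, n = 4), a log2 difference of -0.13 from control (exact permutation p within pairs of arrays = 0.375). The brightest Akt1 probe (NM_009652, chromosome 12) read 5.13 ± 0.032 in control, 5.23 ± 0.255 in AKT1 KO, 5.17 ± 0.104 in AKT2 KO and 5.11 ± 0.076 in DKO hearts (SD, n = 4). Its exact permutation p against control, over swaps within pairs, was 0.625 in AKT1 KO, 0.625 in AKT2 KO and 0.875 in DKO hearts, where 0.125 is the smallest possible. It was called in AKT1 KO hearts with array weights (0.214, limma adjusted p = 0.0473, with 0.0473 to 1 over its alternatives) and in DKO hearts under quantile normalization (-0.354, 0.00126, with 0.00126 to 0.983). The second Akt1 probe differed from control by 0.283 in AKT1 KO and 0.22 in DKO hearts (exact permutation p within pairs = 0.125 and 0.375). Where the Akt1 probes lie relative to the deleted exons, 6 and 7 per the labels, is not known here, so these values do not check the label.

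**Figure D1:**
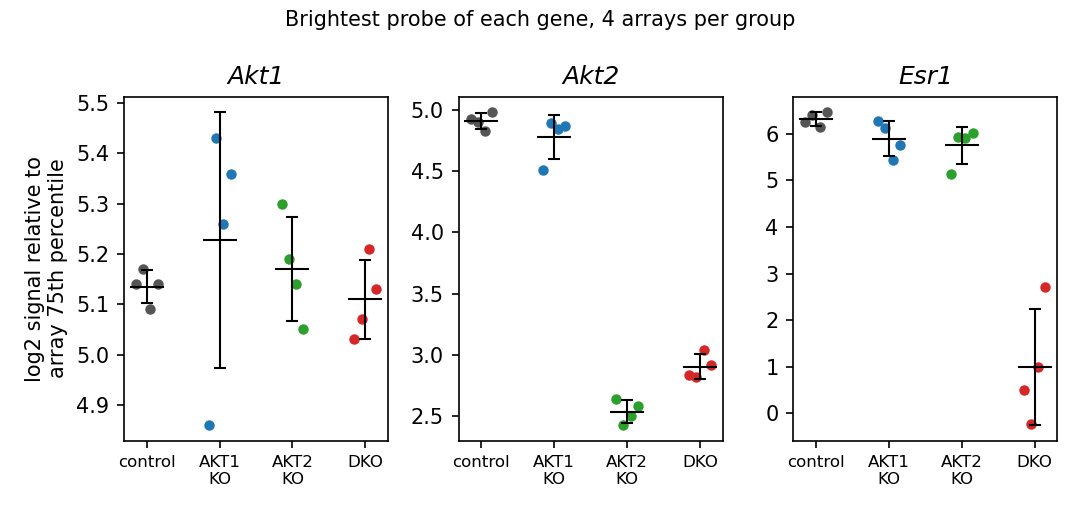
Levels of Akt1, Akt2 and Esr1 (brightest probe of each) as log2 signal relative to the 75th percentile of the array, by group. Points are arrays, lines are means and bars are SD of 4 arrays.

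The comparison of AKT1 KO with control hearts asked what targeting Akt1 alone changed. Ptprn2, which encodes a phosphatase-like protein of secretory vesicles and lies on chromosome 12 like Akt1, rose at least 56.3-fold on its brightest probe (limma adjusted p = 2.77e-08, n = 4 per group) and 2.04-fold on its second kept probe (probe adjusted p = 0.0052). Mybphl, a myosin-binding protein of atrial and conduction cells, rose at least 3.23-fold (adjusted p = 0.00183). Slc38a1, a glutamine transporter, rose by 1.45 ± 0.14 log2 units, and Ppfibp1, a liprin that binds at cell adhesions, by 1.38 ± 0.14 (adjusted p = 0.000169 each). Ocel1, an occludin-domain gene of chromosome 8, rose by 1.82 ± 0.16 (7.34e-05), and Eprn, a noncoding RNA gene, by 2.02 ± 0.25 (0.000925). Zfp963, a zinc finger gene of chromosome 8, rose by 1.94 ± 0.32 (0.00784). Gsta2, a glutathione transferase, fell by 2.61 ± 0.27 log2 units (0.00022), and Plekhh1, a pleckstrin-homology gene of chromosome 12, by 2.65 ± 0.35 (0.00183). A1cf, an RNA-editing cofactor, fell by 2.29 ± 0.35 (0.00525). Sbk3, a predicted kinase of striated muscle, fell by 1.82 ± 0.25 (0.00183), and Cib3, a calcium-binding protein, by 1.66 ± 0.24 (0.00364). Rhd, a red cell membrane protein, fell by 1.61 ± 0.25 (0.00525). Kcnj14, an inward-rectifier potassium channel of chromosome 7, fell by 1.59 ± 0.26 (0.0088), although the mean of its probes was not called (adjusted p = 0.0768, with 0.000398 to 0.398 over its alternatives). Adig, a regulator of fat cell differentiation, fell by 1.39 ± 0.19 (0.00216). Zfp963 was well above background on 2 control arrays, and Plekhh1 on 3 and A1cf on 1 of the AKT1 KO arrays. With normexp background correction the log2 changes were 4.54 for Ptprn2 (main scale, mean of its probes 4.15), 1.43 for Mybphl, 1.04 for Zfp963 and -1.07 for A1cf, and the mean of the probes of Ppfibp1 was 0.744.

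Further AKT1 KO calls ended when 1 array was left out. Nppa, the atrial natriuretic peptide gene, rose from 6.79 ± 0.29 to 8.26 ± 0.20 log2 units (SD, n = 4; change 1.47 ± 0.27 SE, limma adjusted p = 0.0168), but not without control replicate 2 (0.0744) or 3 (0.0646), with 0.00342 to 1 over its alternatives. Ankrd1, a stress-induced ankyrin repeat protein of the sarcomere, rose by 0.715 ± 0.13 (0.0175), a call that ended without control replicate 1, 2 or 4 or AKT1 KO replicate 4 (0.0595 to 0.0762). Insyn2a, a factor of inhibitory synapses, rose at least 2.63-fold (0.0173), but not without control replicate 2 or 3 or AKT1 KO replicate 1 or 4 (0.0512 to 0.0758). Pdlim3, a Z-disc protein that binds alpha-actinin, rose by 1.51 ± 0.31 (0.0379), and 10 arrays ended its call, any of the control or AKT2 KO arrays and AKT1 KO replicates 2 and 4 (0.05 to 0.138). Ifit2, an interferon-induced gene, rose by 0.844 ± 0.16 (0.0242), but not without control replicate 1, 2 or 4 or AKT1 KO replicate 1, 3 or 4 (0.0576 to 0.0926). B3gnt3, a glycosyltransferase, fell by 2.33 ± 0.41 (0.0129), a call lost without control replicate 1 or 2 or AKT1 KO replicate 4 (0.0567 to 0.0603). Fgl1, a secreted fibrinogen-like protein, fell at least 2.2-fold (0.0242), but not without control replicate 1, 2 or 4 or AKT1 KO replicate 2 or 4 (0.0631 to 0.0965). Helt, a transcriptional repressor, fell by 1.43 ± 0.30 (0.0358), lost without any control array, AKT1 KO replicate 2 or 4 or AKT2 KO replicate 1 (0.0506 to 0.13) and under quantile normalization (0.0558), with 0.000102 to 0.561 over its alternatives. Gsta4, a glutathione transferase, fell by 0.545 ± 0.11 (0.0273), but not without any control array or AKT1 KO replicate 4 (0.0709 to 0.115). Egr1, an immediate early transcription factor, fell by 1.20 ± 0.26 (0.0468), and 12 arrays ended its call, any control or AKT1 KO array, AKT2 KO replicate 3 and DKO replicates 1, 2 and 4 (0.0562 to 0.164). Without the filter on dim probes 9 of these 10 calls also ended, all but that of B3gnt3. With only the groups compared in the fit those of B3gnt3 and Fgl1 ended, in the authors' values those of Helt and Egr1, and with slide and row as a block that of Ifit2 (0.0505, with 0.000182 to 1 over its alternatives). The Egr1 call also ended under quantile normalization, with the mean of its probes and with slide as a block. B3gnt3 was well above background on 1 AKT1 KO and 3 control arrays, with -0.829 under normexp, and Fgl1 on 3 control arrays, with -0.81. Insyn2a had 0.958 with normexp.

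In all, limma called 109 of 13725 genes (57 higher, 52 lower) in AKT1 KO hearts, 46 of them by at least 2-fold. It called 109 with slide but not row as a block, 14 within slide 1 and 4 within slide 2. The count was 822 with array weights (392 higher, 430 lower), 182 with only the groups compared in the fit and 56 without the filter on dim probes. Leaving out 1 array moved it to 56, 54, 63 or 64 (control replicates 1 to 4), 56 (AKT1 KO replicate 4) or 291 (DKO replicate 3). Chromosome 8 held 23 of the 109 genes, 21.1% against 5.3% of the genes tested (2-sided Fisher exact p = 9.97e-09, 7.67e-07 after correction over chromosomes and comparisons). Within 10 Mb of Akt1, 4 of 108 genes were called, Zfp386, Wdr60, Ncapg2 and Ptprn2, against 105 of 13615 elsewhere (one-sided Fisher exact p = 0.0107). The first 3 of these 4 were named after their values were seen. Called genes had a called neighbour within 2 Mb in 45 of 109 cases, against a mean of 28.4 in 10000 random draws of expressed genes (permutation p = 0.005).

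**Figure D2:**
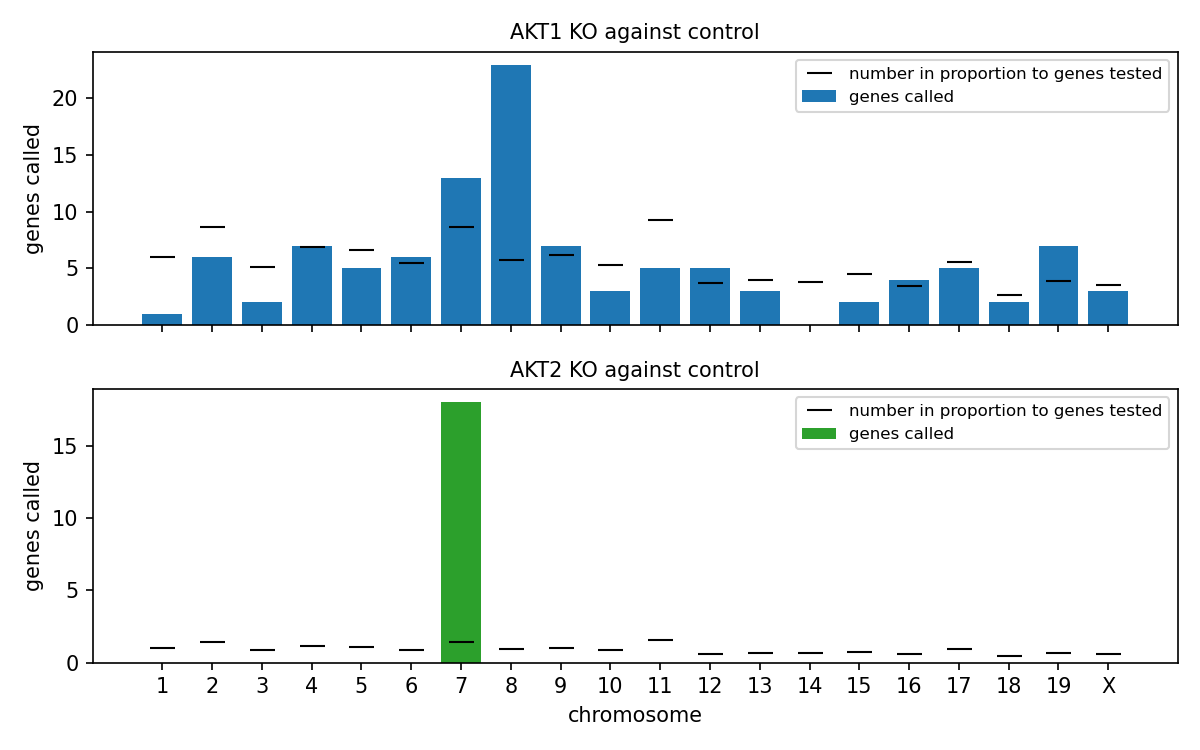
Number of genes called per chromosome (bars) in AKT1 KO and in AKT2 KO against control hearts, 4 arrays per group. Black dashes mark the number in proportion to the genes tested, and chromosome 8 held 23 calls in AKT1 KO and chromosome 7 held 18 in AKT2 KO hearts.

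At the preset correlation only, oxidative metabolism lists lay slightly lower in AKT1 KO hearts. Fatty acid oxidation had a median log2 change of -0.209 (-0.197 on slide 1 and -0.256 on slide 2) with 0 of 31 genes called and 3 adjusted over the list alone (camera adjusted p = 5.83e-05, but adjusted p = 0.714 with an estimated correlation). Oxidative phosphorylation had a median of -0.105 (slides -0.033 and -0.176) with 0 of 42 called and 0 adjusted over the list alone (camera adjusted p = 0.000268, but adjusted p = 0.807 with an estimated correlation). The tricarboxylic acid cycle list had a median of -0.096 (slides -0.042 and -0.128) with 0 of 23 called and 1 adjusted over the list alone (0.0171, but adjusted p = 0.807 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.11 (slides -0.034 and -0.175) with 0 of 31 called and 0 adjusted over the list alone (0.000947, but adjusted p = 0.807 with an estimated correlation). The oxidative stress list had a median of -0.108 (slides -0.028 and -0.184), with Gsta4 as the 1 of 28 called and 2 adjusted over the list alone (0.0343, but adjusted p = 0.807 with an estimated correlation). Immediate early genes had a median of -0.297 (slides -0.221 and -0.385), with Egr1 as the 1 of 24 called and 6 adjusted over the list alone (6.23e-06, but adjusted p = 0.594 with an estimated correlation). The AKT1 KO shift of the fetal and stress gene list was upward by mean (0.163) and test, while its median was -0.019 (slides 0.116 and -0.10; 0.064 under quantile normalization and 0.041 in the authors' values). It held 2 called genes of 24, Nppa and Ankrd1, and 4 adjusted over the list alone (camera adjusted p = 0.00505, but adjusted p = 0.714 with an estimated correlation). Interferon response genes had a median of 0.122 (slides 0.226 and -0.051), with Ifit2 as the 1 of 27 called (0.0124, but adjusted p = 0.807 with an estimated correlation). The 5 neutrophil markers had a median of 0.248 (slides 0.485 and 0.443) and none was called (0.0473, but adjusted p = 0.582 with an estimated correlation). Under quantile normalization the medians were -0.116 for fatty acid oxidation, -0.0103 for oxidative phosphorylation, -0.00506 for the tricarboxylic acid cycle, -0.0201 for ribosomal proteins and -0.0555 for oxidative stress. Without AKT1 KO replicate 1 they were -0.119, -0.0232, -0.00155, -0.0512 and -0.036, and in the authors' values -0.124, -0.0175, 0.00155, -0.0218 and -0.0533. The interferon median was 0.0779 with normexp and 0.189 without that array, and the fetal and stress median 0.0886 without it. In AKT1 KO hearts 27 lists did not pass, among them AKT pathway components (median -0.035, 0 of 31 called, adjusted p = 0.397) and FoxO target genes (median -0.092, 0 of 29 called, adjusted p = 0.153). Of these, atrial markers had a median of -0.051 and a mean of 0.156, and mesothelial and epicardial markers of 0.017 and -0.251. Over all genes 1017 had an unadjusted p under 0.05, against 686 expected by chance.

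The comparison of AKT2 KO with control hearts asked what targeting Akt2 alone changed, and all of the 18 genes limma called lay on chromosome 7, which carries Akt2, within 19 Mb of it. Kcnj14, the inward-rectifier potassium channel that fell in AKT1 KO hearts, rose 29.9-fold (log2 change 4.90 ± 0.26 SE, limma adjusted p = 1.09e-07, n = 4 per group). The kallikrein genes Klk1b22 and Klk1b3, which encode secreted proteases, rose at least 7.84-fold and at least 4.13-fold (0.00118 and 0.00526). Bcat2, the mitochondrial enzyme that starts the breakdown of branched-chain amino acids, rose by 1.88 ± 0.16 log2 units (2.47e-05), and Ush1c, a scaffold protein of sensory hair cells, by 2.32 ± 0.30 (0.00219). Blvrb, a biliverdin reductase, rose by 0.915 ± 0.09 (0.000116), and Lrrc4b, a synaptic adhesion protein, by 1.43 ± 0.17 (0.000846). Zfp420, a zinc finger gene, rose by 1.70 ± 0.23 (0.0037), and Gmfg, an actin regulator of blood cells, by 0.877 ± 0.13 (0.0072). Mamstr, a coactivator of the muscle transcription factor MEF2, fell by 1.25 ± 0.093 (6.59e-06), and Mrps12, a mitochondrial ribosomal protein, by 1.06 ± 0.09 (2.47e-05). Pop4, a subunit of ribonuclease P, had a log2 change of -2.25 ± 0.27 (0.000907), and Ftl1, the ferritin light chain, fell by 1.0 ± 0.14 (0.00565). The call of Klk1b26, a rise of 1.35 ± 0.24 (0.0349), was lost without control replicate 1, 2 or 3, AKT1 KO replicate 3, any AKT2 KO array or DKO replicate 2 (0.0514 to 0.172). Sertad3, a transcriptional coactivator, fell by 0.58 ± 0.095 (0.0193), but not without control replicate 1, 2 or 3 or AKT2 KO replicate 1, 2 or 4 (0.058 to 0.112). Map3k10, a kinase of the JNK pathway, fell by 0.476 ± 0.075 on its brightest probe (0.0146), while the mean of its 3 probes was -0.101, and the call was lost without control replicate 1 or 4 or AKT2 KO replicate 3 or 4 (0.0523 to 0.0827). Alkbh6, a member of the AlkB demethylase family, fell by 0.436 ± 0.074 (0.0287), but not without any control or AKT2 KO array or AKT1 KO replicate 4 (0.0556 to 0.134). With replicate number as a block these 4 calls also ended, for Klk1b26 at 0.0699, Sertad3 at 0.0731, Map3k10 at 0.0673 and Alkbh6 at 0.0731 (0.00376 to 1, 0.00012 to 1, 0.000592 to 1 and 0.000124 to 1 over their alternatives). All 4 ended without the filter on dim probes, Map3k10 and Alkbh6 with slide and row as a block, Klk1b26 and Sertad3 under quantile normalization and in the authors' values, and Sertad3 with normexp. Normexp values were 1.94 for Klk1b22, 1.51 for Klk1b3, 0.601 for Zfp420, which was well above background on 1 control array, 0.839 for Klk1b26 and -0.751 for Mamstr.

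The 18 AKT2 KO calls (10 higher, 8 lower, Akt2 among them) came from 1093 genes tested on chromosome 7 (Fisher exact p = 1.46e-20, corrected 2.24e-18), and 13 of the 18 changed by at least 2-fold. Within 10 Mb of Akt2, 7 of 250 other genes were called against 10 of 13473 elsewhere (one-sided Fisher exact p = 1.02e-08). Of the 17 called genes other than Akt2, 13 were called in the same direction in DKO hearts. Klk1b26 and Lrrc4b were called in the opposite direction and Ftl1 and Sertad3 were not called. Calls were 19 with slide as a block, 11 and 3 within slides 1 and 2, and 37 without DKO replicate 3. They were 93 with array weights (38 higher, 55 lower) and 42 with only the groups compared. Quantile normalization gave 10 higher and 13 lower, 43.5% against 55.6% higher. Off chromosomes 7, 8 and 12 limma called 0 of 11438 genes, with 314 at an unadjusted p under 0.05 (572 by chance). The fit included the wider DKO spread, so changes there stay open.

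At the preset correlation only, immune and matrix lists lay higher and muscle and oxidative metabolism lists lower in AKT2 KO hearts. Of the 13 passing lists limma called 0 members and fry 0. Inflammation and cytokines had a median log2 change of 0.214 over 26 genes (0.382 on slide 1 and 0.050 on slide 2; camera adjusted p = 2.7e-06, but adjusted p = 0.582 with an estimated correlation). Lymphocyte markers had a median of 0.441 over 10 genes (slides 0.693 and -0.021; 0.00546, adjusted p = 0.676 with an estimated correlation), and neutrophil markers of 0.359 over 5 (slides 0.496 and 0.222; 0.0058, adjusted p = 0.582 with an estimated correlation). Macrophage and myeloid markers had a median of 0.114 (slides 0.367 and -0.126; 0.00267, adjusted p = 0.772 with an estimated correlation), and interferon response genes of 0.138 (slides 0.355 and -0.091; 0.00471, adjusted p = 0.807 with an estimated correlation). Cell cycle genes had a median of 0.16 (slides 0.397 and -0.058; 0.00243, adjusted p = 0.714 with an estimated correlation), and extracellular matrix and fibrosis genes of 0.134 (slides 0.162 and 0.071; 0.000263, adjusted p = 0.784 with an estimated correlation). Oxidative phosphorylation had a median of -0.115 (slides -0.171 and -0.058; 9.4e-09, adjusted p = 0.714 with an estimated correlation), and the tricarboxylic acid cycle of -0.083 (slides -0.15 and -0.047; 0.000582, adjusted p = 0.772 with an estimated correlation). Fatty acid oxidation had a median of -0.108, with 1 gene called adjusted over the list alone (slides -0.175 and -0.040; 0.000947, adjusted p = 0.772 with an estimated correlation). Calcium handling and ion channel genes had a median of -0.121 (slides -0.159 and -0.077; 0.003, adjusted p = 0.676 with an estimated correlation), and sarcomere genes of -0.102 (slides -0.139 and -0.067; 0.0108, adjusted p = 0.714 with an estimated correlation). Autophagy and proteasome genes had a median of -0.068 (slides -0.097 and -0.031; 0.0108, adjusted p = 0.807 with an estimated correlation). In the authors' values the medians were -0.0041 for sarcomere genes, -0.0757 for calcium handling, -0.0453 for fatty acid oxidation, -0.0316 for oxidative phosphorylation, -0.0316 for the tricarboxylic acid cycle and -0.0325 for autophagy and proteasome genes. Under quantile normalization they were -0.0269 for sarcomere genes, -0.08 for calcium handling, -0.0555 for oxidative phosphorylation and -0.0513 for the tricarboxylic acid cycle, and with normexp 0.156 for lymphocyte markers and 0.106 for cell cycle genes. The other 23 lists did not pass, among them AKT pathway components (median -0.025, Akt2 the 1 of 31 called, 0.282) and FoxO target genes (median -0.032, 0 of 29 called, 0.357). Over all genes 443 had an unadjusted p under 0.05 (686 by chance, with DKO arrays in the fit).

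The comparison of DKO with control hearts asked what targeting both genes changed. Gdf15, a secreted stress cytokine, rose 62.3-fold, from -1.40 ± 0.13 to 4.56 ± 0.91 log2 units (SD, n = 4; change 5.96 ± 0.36 SE, limma adjusted p = 2.67e-08). Ccn2, a matrix-associated growth factor, rose from 3.24 ± 0.044 to 8.33 ± 0.197 (change 5.09 ± 0.19 SE, 4.33e-10). Sprr1a, a small proline-rich protein induced by stress in cardiomyocytes, rose at least 17.6-fold (2.83e-06), and Lgals3, a galectin of macrophages, by 4.10 ± 0.17 log2 units (1.28e-09). Nmrk2, a muscle kinase that makes NAD from nicotinamide riboside, rose by 4.04 ± 0.43 (4.08e-06), Plekha7, a protein of adherens junctions, by 4.28 ± 0.45 (4.43e-06), and Cxcr6, a chemokine receptor, by 4.12 ± 0.48 (1.17e-05). Ptprn2 rose at least 18.4-fold on its brightest probe (3.7e-08), while its second kept probe differed by 0.243 (probe adjusted p = 0.23). Plcxd2, a phospholipase-like gene, rose at least 7.25-fold (1.2e-08) and Sepsecs, an enzyme that makes selenocysteine tRNA, at least 6.49-fold (2.66e-06), although without the filter on dim probes another Sepsecs probe took its place with -0.030. Trim12a, a tripartite motif gene of chromosome 7, fell at least 42.2-fold (1.28e-09). Efnb3, an ephrin ligand, fell by 4.41 ± 0.24 (1.07e-08), and Lgals4, a galectin, by 4.01 ± 0.46 (9.91e-06). Igsf1, an immunoglobulin-domain protein, had a log2 change of -3.76 ± 0.23 (2.86e-08), Cryba4, a crystallin, of -3.75 ± 0.16 (1.34e-09) and Prr33, a proline-rich protein, of -3.70 ± 0.17 (1.54e-09). The crystallin Crybb1 fell at least 4.06-fold (2.67e-08) and A1cf fell at least 3.98-fold (7.34e-07). A probe annotated to Esr1, the oestrogen receptor gene, fell from 6.32 ± 0.15 to 0.992 ± 1.25 (SD, n = 4; change -5.33 ± 0.44 SE, 5.29e-07). Plekha7 was well above background on 1 control array and Cxcr6 on 3, and Cryba4 on 2 DKO arrays. With normexp background correction the log2 changes were 2.84 for Sprr1a, 3.02 for Ptprn2 (main scale, mean of its probes 2.95), 2.61 for Plekha7, 1.81 for Plcxd2, 1.74 for Sepsecs, -4.56 for Trim12a, and -1.52 for Crybb1 and for A1cf.

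In all 6257 of 13725 genes (45.6%) were called in DKO hearts, 3354 higher and 2903 lower, and 495 rose and 636 fell by at least 2-fold. With slide as a block 6593 genes were called, with 5648 within slide 1 and 2464 within slide 2.

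Genes of mitochondrial fuel use fell together in DKO hearts. Of 31 fatty acid oxidation genes 25 fell and 0 rose (25 and 0 adjusted over the list alone), with a median log2 change of -1.14 (-1.20 on slide 1 and -0.943 on slide 2; camera adjusted p = 1.16e-11, but adjusted p = 0.582 with an estimated correlation). Among them were Cpt2, which completes the import of fatty acids into mitochondria (-2.08 ± 0.13 SE, limma adjusted p = 4.25e-08), Ech1, an isomerase of unsaturated fatty acids (-2.06 ± 0.11, 1.07e-08), and the dehydrogenases Acads (-1.65 ± 0.11, 7.26e-08) and Hadh (-1.59 ± 0.10, 5.36e-08). Of 42 oxidative phosphorylation genes 42 fell (42 adjusted over the list alone), with a median of -0.554 (slides -0.607 and -0.519; 5.26e-16, but adjusted p = 0.594 with an estimated correlation). Examples were Ndufa9 of complex I (-1.0 ± 0.087), Uqcrc1 of complex III (-1.01 ± 0.094) and Cox7a1 of complex IV (-1.37 ± 0.14). Of 23 tricarboxylic acid cycle genes 22 fell (22 adjusted over the list alone), with a median of -0.688 (slides -0.678 and -0.706; 1.98e-11, but adjusted p = 0.582 with an estimated correlation). Examples were Sucla2, a succinyl-CoA ligase subunit (-1.51 ± 0.12), Pdhx of the pyruvate dehydrogenase complex (-1.14 ± 0.095), the pyruvate carrier Mpc2 (-1.10 ± 0.094) and citrate synthase, Cs (-0.685 ± 0.071). Of 22 mitochondrial regulators 14 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.445 (slides -0.329 and -0.504; 0.000581, but adjusted p = 0.676 with an estimated correlation). Examples were the fusion protein Opa1 (-0.908 ± 0.11), the deacetylase Sirt3 (-1.01 ± 0.16) and Tfam and Polrmt, which transcribe mitochondrial DNA (-0.564 ± 0.084 and -0.723 ± 0.11). Glycolysis and glucose use did not pass as a list (median -0.282, slides -0.291 and -0.16, 6 rose and 16 fell of 31, 6 and 16 adjusted over the list alone, 0.0875). In it the glucose transporter Slc2a1 rose by 1.68 ± 0.11 (5.36e-08). Pfkfb1 and Pfkm, which control the phosphofructokinase step, fell by 2.10 ± 0.21 and 1.36 ± 0.17, as did Ldhb, a lactate dehydrogenase (-0.863 ± 0.11). Sterol and lipid synthesis did not pass (median 0.027, slides 0.253 and -0.0419, 7 rose and 3 fell of 22, 0.659). It included rises of the desaturase Scd1 (1.77 ± 0.11), of Lss (1.44 ± 0.26, 0.83 with normexp, on 3 control arrays above background) and of Acly (0.373 ± 0.076) and a fall of Cyp51 (-0.96 ± 0.18).

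Genes of the excitable and contractile apparatus moved unevenly in DKO hearts. Of 34 calcium handling and ion channel genes 24 fell and 2 rose (25 and 3 adjusted over the list alone), with a median of -0.85 (slides -0.761 and -0.848; camera adjusted p = 7.41e-08, but adjusted p = 0.582 with an estimated correlation). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell by 1.97 ± 0.19 SE, and Trdn, which anchors calsequestrin to the release channel, by 1.04 ± 0.08. The potassium channel genes Kcnh2 and Kcnd3 fell by 1.44 ± 0.14 and 0.949 ± 0.092. Sarcomere genes did not pass as a list (median -0.318, -0.163 under quantile normalization and -0.113 in the authors' values, 12 fell and 4 rose of 25, 13 and 5 adjusted over the list alone, 0.0875). These included falls of Nebl (-0.642 ± 0.098) and Tnni3, cardiac troponin I (-0.649 ± 0.11, -0.369 in the authors' values), and rises of Csrp3 (0.66 ± 0.12) and Myom2 (0.556 ± 0.10). Of 24 fetal and stress genes 17 rose and 2 fell (17 and 3 adjusted over the list alone), with a median of 1.24 (slides 0.705 and 1.48, and 0.82 without DKO replicate 3; 9.99e-06, but adjusted p = 0.582 with an estimated correlation). Beside Ccn2 and Gdf15 these included Ankrd1 (2.19 ± 0.13, 2.76e-08) and Rcan1, an inhibitor of calcineurin (2.07 ± 0.14, 5.46e-08). Of 8 skeletal muscle markers 5 fell (5 adjusted over the list alone), with a median of -0.652 (slides -0.859 and -0.461; 0.0136, but adjusted p = 0.582 with an estimated correlation). Of these Ckm, the creatine kinase that cardiomyocytes also make, fell by 2.01 ± 0.18, the myosin light chain gene Myl1 by 1.39 ± 0.16, and the fast troponin genes Tnni2 and Tnnc2 by 1.66 ± 0.22 and 0.753 ± 0.22 (Tnnc2 -0.453 with normexp). Atrial markers did not pass as a list (median 0.397, 4 rose and 2 fell of 8, 5 and 2 adjusted over the list alone, 0.296). Nppa rose by 2.49 ± 0.27 (5.59e-06), Dkk3, a Wnt inhibitor, by 2.0 ± 0.21 and Nr2f2, an atrial transcription factor, by 0.429 ± 0.092, and Stard10, a lipid transfer protein, fell by 0.647 ± 0.095.

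Matrix, ribosomal and inflammatory genes rose in DKO hearts. Of 37 extracellular matrix and fibrosis genes 33 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 1.41 (slides 0.974 and 1.56, and 0.977 without DKO replicate 3; camera adjusted p = 7.72e-11, but adjusted p = 0.594 with an estimated correlation). The growth factors Tgfb2 and Tgfb3 rose by 2.82 ± 0.17 SE (limma adjusted p = 2.86e-08) and 0.90 ± 0.066, and Thbs4, a matricellular protein, by 1.80 ± 0.17. Fibroblast markers rose in 10 of 15 cases (10 adjusted over the list alone), with a median of 0.525 (slides 0.551 and 0.481; 0.00279, but adjusted p = 0.582 with an estimated correlation). Among them were Dpt (0.677 ± 0.08), Dcn (0.525 ± 0.076, 0.331 under quantile normalization), Pdgfra (0.694 ± 0.10) and Meox1 (0.965 ± 0.18). Of 31 cytosolic ribosomal protein genes 30 rose (30 adjusted over the list alone), with a median of 0.638 (slides 0.461 and 0.784, and 0.338 under quantile normalization; 1.55e-12, but adjusted p = 0.594 with an estimated correlation). Examples were Rpl3 (1.56 ± 0.15), Rpl5 (0.821 ± 0.09), Rpl10 (0.821 ± 0.074) and Rps4x (0.775 ± 0.074), with 0.48 for Rpl5 and 0.36 for Rps4x under quantile normalization. Of 26 inflammation and cytokine genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.719 (slides 0.62 and 0.788; 0.00275, but adjusted p = 0.582 with an estimated correlation). The chemokines Ccl8 and Cxcl10 rose by 2.20 ± 0.38 and 1.87 ± 0.36 (Cxcl10 1.13 with normexp, on 3 control arrays above background), and the cytokine receptors Osmr and Il1r1 by 1.32 ± 0.25 and 0.513 ± 0.083. Of 24 macrophage and myeloid markers 12 rose (14 adjusted over the list alone), with a median of 0.489 (slides 0.589 and 0.433; 0.0104, but adjusted p = 0.807 with an estimated correlation). Among them were Laptm5 (0.676 ± 0.19), Lyz1 (0.586 ± 0.17) and Cd14 (0.551 ± 0.16). Interferon response genes did not pass (median 0.224, slides 0.484 and -0.024, 4 of 27 rose, 0.0987). The 4 were Ifit2 (1.94 ± 0.16), Ifi27l2a (0.85 ± 0.21), Ifit1 (0.752 ± 0.198) and Ddx58 (0.383 ± 0.11), but the mean of the 3 Ddx58 probes, 0.215, was not called (limma adjusted p = 0.207, with 0.000978 to 0.207 over its alternatives). Without DKO replicate 3 the count was 16 and the median 0.529.

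Other cell type lists did not pass in DKO hearts, although single members were called. Endothelial markers had a median of 0.121 (slides 0.034 and 0.167, -0.091 under quantile normalization), and 3 rose and 1 fell of 20 (3 and 1 adjusted over the list alone, camera adjusted p = 0.484). Vwf, which endothelial cells store and secrete, rose by 0.872 ± 0.16 SE, Ly6c1 by 0.474 ± 0.12, and Aqp1, a water channel, by 0.306 ± 0.094. Under quantile normalization neither was called, with 0.0702 for Ly6c1 (limma adjusted p = 0.607, 0.00127 to 0.607 over its alternatives) and -0.096 for Aqp1, whose call also ended in the authors' values (0.188). The growth factor receptor gene Kdr fell by 0.418 ± 0.13, but was not called with only the groups compared in the fit (0.0699, with 0.00256 to 0.121 over its alternatives). Its value was -0.253 without DKO replicate 3 and -0.259 with array weights. Smooth muscle and pericyte markers had a median of 0.099 (slides 0.30 and -0.0119), with 4 higher and 3 lower of 13 (0.729). Of these Des, which cardiomyocytes also make, rose by 1.29 ± 0.15, Tagln rose by 0.758 ± 0.16, and Smtn fell by 1.02 ± 0.14. The brightest probe of Acta2, smooth muscle actin, fell by 0.491 ± 0.13, although the mean of its 3 probes was 0.412, and its change was -0.891 under quantile normalization. Adipocyte markers had a median of 0.207 (mean 0.482, slides -0.0095 and 0.424, -0.177 under quantile normalization) while the test pointed down (0.938). Cfd, a complement protease, rose by 2.31 ± 0.66 and Cidec, a lipid droplet protein, at least 1.93-fold (log2 change 0.661 with normexp), while Adig, well above background on 3 DKO arrays, fell by 2.67 ± 0.19 (-1.65 with normexp) and Lep, the leptin gene, by 0.482 ± 0.14. Lymphocyte markers had a median of 0.275 (slides 0.501 and 0.0381), with 2 of 10 called and 0 adjusted over the list alone (0.601). The protease gene Gzma rose by 0.85 ± 0.28 but not without control replicate 2 or DKO replicate 2 (limma adjusted p = 0.0674 and 0.0794, with 0.00489 to 0.132 over its alternatives). Cd52 rose by 0.935 ± 0.32 but not without control replicate 1 or 4 or DKO replicate 2 (0.0587 to 0.0924). Both calls also ended without the filter on dim probes, and Gzma had 0.489 with normexp. Neutrophil markers had a median of 0.449 (slides 0.772 and 0.126) with 0 of 5 called (0.87). Schwann cell and neuron markers had a median of 0.239 (slides 0.394 and 0.173), with 4 higher and 2 lower of 9 (0.845). Dbh and Th, enzymes of noradrenaline synthesis, fell by 2.48 ± 0.19 and 0.811 ± 0.14, and Uchl1, a ubiquitin hydrolase, rose by 1.20 ± 0.23. The myelin gene Mbp rose by 0.74 ± 0.24 but not without DKO replicate 2 (0.0647, with 0.00695 to 0.269 over its alternatives), and its value was 0.476 with normexp. Mesothelial and epicardial markers had a median of 0.244 (slides -0.0347 and 0.522) with Krt18, a keratin, as the 1 of 4 that rose (3.12 ± 0.27; 0.375). Erythroid markers had a median of -0.021 (slides 0.40 and -0.299) and a mean of 0.204, with Hbb-b2, a globin, as the 1 of 6 that rose (1.51 ± 0.28; 0.844).

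Signalling and stress lists gave mixed results in DKO hearts. AKT pathway components had a median of -0.022 and a mean of 0.082, with 7 higher and 6 lower of 31 (camera adjusted p = 0.87). The receptor genes Igf1r and Insr rose by 2.10 ± 0.11 SE (limma adjusted p = 8.86e-09) and 1.0 ± 0.11, and Pik3cb, a catalytic subunit of PI3-kinase, by 0.928 ± 0.076. FoxO target genes had a median of 0.104 (slides 0.321 and 0.225, 0.0345 under quantile normalization and 0.232 without DKO replicate 3), with 10 higher and 2 lower of 29 (0.123). Called members were Nt5e (1.72 ± 0.13), Eif4ebp1, an inhibitor of translation (1.64 ± 0.16), and the autophagy genes Bnip3 and Gabarapl1 (1.19 ± 0.11 and 1.19 ± 0.097). Of 24 immediate early genes 11 rose (13 adjusted over the list alone), with a median of 0.688 (slides 0.378 and 1.04; 0.0014, but adjusted p = 0.714 with an estimated correlation). Among them were Myc (3.24 ± 0.37, on 3 control arrays above background), Maff (2.61 ± 0.22), Junb (1.37 ± 0.13) and Klf6 (1.14 ± 0.21). Of 28 apoptosis regulators 11 rose (11 adjusted over the list alone), with a median of 0.309 (slides 0.376 and 0.227; 0.0118, but adjusted p = 0.582 with an estimated correlation). Examples were Tnfrsf12a, the receptor of TWEAK (2.22 ± 0.19), Casp12 (0.847 ± 0.11), Bok (0.90 ± 0.13) and Bax (0.559 ± 0.086). Oxidative stress response genes did not pass (median 0.427, slides 0.206 and 0.542, 0.239 without DKO replicate 3, 17 rose and 5 fell of 28, 18 and 5 adjusted over the list alone, 0.101). The secreted peroxidase Gpx3 rose by 3.24 ± 0.10 (8.59e-11), and Sod2, Gsta4 and Prdx3, of which Sod2 and Prdx3 are mitochondrial, fell by 1.29 ± 0.16, 0.969 ± 0.11 and 0.795 ± 0.092. The integrated stress and unfolded protein list had a median of 0.265 (0.0444 under quantile normalization), with 13 higher and 5 lower of 30 (0.229). It included rises of Xbp1 (1.04 ± 0.088) and Psat1 (2.05 ± 0.31) and a fall of Aldh1l2 (-1.92 ± 0.21, -1.16 with normexp, on 3 DKO arrays above background). Autophagy and proteasome genes had a median of 0.121 (slides 0.053 and 0.183, 0.0015 under quantile normalization), with 13 higher and 3 lower of 33 (0.146). These included a rise of Sqstm1 (0.841 ± 0.11, 0.471 under quantile normalization) and a fall of Map1lc3a (-0.828 ± 0.10). The p53 response list had a median of 0.247, with 8 higher and 3 lower of 21 (9 and 3 adjusted over the list alone, 0.197). It included rises of Phlda3 (0.90 ± 0.11) and Perp (1.02 ± 0.17, 0.585 under quantile normalization) and a fall of Ccng1 (-1.41 ± 0.13). Hypoxia response and angiogenic factors had a median of -0.0046 (slides 0.118 and 0.125) and a mean of 0.138, with 9 higher and 5 lower of 25 (0.411). These included a rise of Ndrg1 (1.26 ± 0.197) and a fall of Apln, the apelin gene (-1.72 ± 0.12). The circadian clock list had a median of -0.0024 and a mean of 0.018 (slide medians -0.187 and 0.0707), with 4 higher and 3 lower of 21 (3 and 3 adjusted over the list alone, 0.983). It included falls of Ciart (-1.94 ± 0.26, -0.769 with normexp, on 1 DKO array above background) and Usp2 (-0.996 ± 0.15) and rises of Rora (0.523 ± 0.06) and Tspan4 (1.83 ± 0.28). Cell cycle genes had a median of 0.027 (-0.035 with normexp background correction, -0.168 without DKO replicate 3) and a mean of -0.032, with 5 higher and 3 lower of 23 (5 and 2 adjusted over the list alone, 0.942). These included rises of Tyms (0.563 ± 0.15), Pcna (0.41 ± 0.089) and Mcm4 (0.298 ± 0.077) and a fall of Cenpa (-0.889 ± 0.12).

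**Figure D3:**
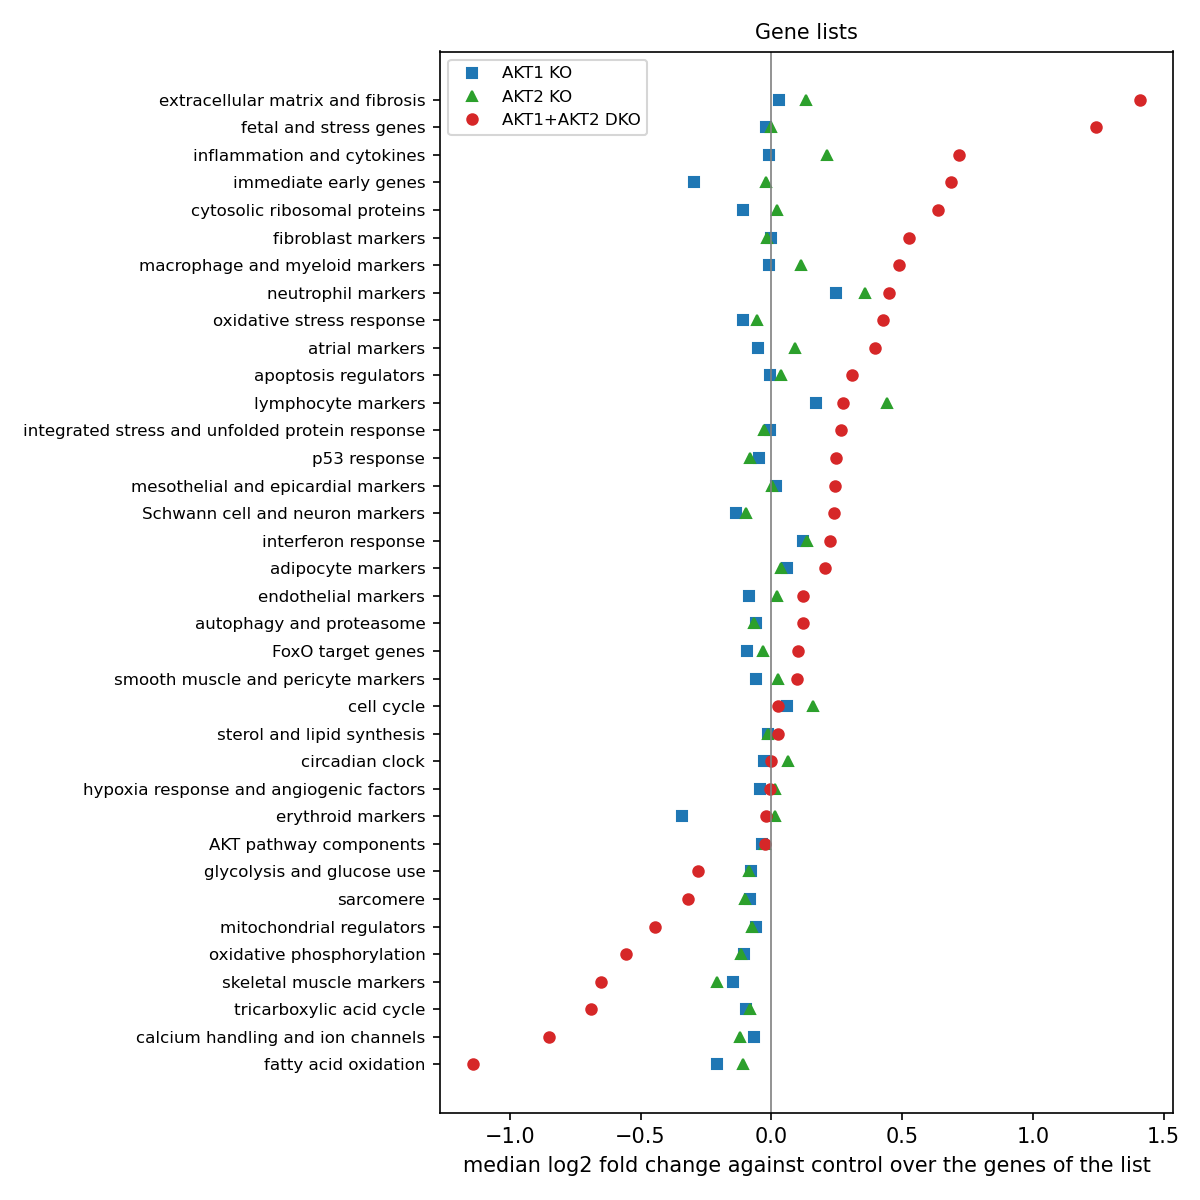
Median log2 fold change of the 36 gene lists in AKT1 KO (squares), AKT2 KO (triangles) and DKO (circles) hearts against control, 4 arrays per group. Under quantile normalization the DKO medians of endothelial markers (-0.091) and adipocyte markers (-0.177) changed sign, as did the AKT1 KO medians of fetal and stress genes (0.064) and sarcomere genes (0.014) and further medians near 0.

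The comparisons of DKO with each single knockout asked what targeting the second gene added. Against AKT1 KO hearts 6450 genes were called in DKO hearts (3661 higher, 2789 lower), or 4195 with only the groups compared in the fit. Gdf15 was higher by 5.19 ± 0.36 log2 units (SE, limma adjusted p = 9.61e-08, n = 4 per group), Ccn2 by 4.25 ± 0.19 (1.38e-09), Kcnj14 by 4.62 ± 0.26 (2.06e-08), Sprr1a at least 20.5-fold and Plcxd2 at least 8.54-fold. Trim12a was lower at least 45-fold (9.82e-10) and Crybb1 at least 4.18-fold. The differences were -4.91 ± 0.44 for Esr1 (1.15e-06), -4.30 ± 0.24 for Efnb3 (1.5e-08) and -3.87 ± 0.595 for Cyp2b10, a cytochrome P450 (0.000115), which was well above background on 2 DKO arrays and had -2.24 with normexp. With normexp Sprr1a had 3.05, Plcxd2 2.0, Trim12a -4.58 and Crybb1 -1.54. Against AKT2 KO hearts 5780 genes were called in DKO hearts (3228 higher, 2552 lower). Gdf15 was higher by 5.67 ± 0.36 (5.27e-08), Ccn2 by 4.79 ± 0.19 (1.03e-09), Sprr1a by 4.60 ± 0.47 (4.22e-06, 2.95 with normexp, on 1 AKT2 KO array above background) and the brightest Ptprn2 probe at least 21.7-fold (6.74e-08). Trim12a was lower at least 30.6-fold (2.99e-09) and Klk1b26 at least 5.23-fold. With normexp Ptprn2 had 3.09 (main scale, mean of its probes 2.73), Trim12a -4.04 and Klk1b26 -1.81. The differences were -4.76 ± 0.44 for Esr1 (1.66e-06) and -4.27 ± 0.24 for Efnb3 (1.9e-08). With slide as a block the counts were 6812 against AKT1 KO and 6044 against AKT2 KO, with 5997 and 4966 within slide 1 and 2715 and 1903 within slide 2.

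Compared with each other, AKT2 KO and AKT1 KO hearts differed in 123 genes (57 higher and 66 lower in AKT2 KO), 30 on chromosome 7 and 24 on chromosome 8 (Fisher exact, corrected p = 9.29e-07 each). Kcnj14 was higher in AKT2 KO hearts by 6.49 ± 0.26 log2 units (SE, limma adjusted p = 1.38e-09, n = 4 per group), Klk1b3 at least 4.86-fold (0.00373), Klk1b22 by 3.1 ± 0.49 (0.00435, 1.78 with normexp, on 2 AKT1 KO arrays above background), Gsta2 by 2.46 ± 0.27 (0.000228) and Fgl1 at least 2.5-fold (0.0106). The Fgl1 call ended with only the groups compared in the fit. The brightest Ptprn2 probe was lower at least 66.1-fold (2.15e-08), Mybphl at least 3.8-fold (0.00312), and Insyn2a at least 3.09-fold (0.00533). The difference was -2.24 ± 0.089 for Akt2 (1.38e-09) and -2.13 ± 0.27 for Pop4 (6e-04). With slide as a block 124 genes were called, with 46 within slide 1 and 8 within slide 2, 328 without DKO replicate 3, 849 with array weights and 81 without the filter on dim probes. With normexp Ptprn2 had -4.61 (main scale, mean of its probes -3.93), Klk1b3 1.47, Mybphl -1.31, Insyn2a -1.15 and Fgl1 0.809.

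The departure from additivity asked whether the DKO change differed from the sum of the 2 single knockout changes on the log2 scale, and it was called for 3566 genes (2177 above the sum, 1389 below). Gdf15 exceeded the sum by 4.90 ± 0.51 log2 units (SE, limma adjusted p = 1.76e-05, n = 4 per group) and Ccn2 by 3.95 ± 0.26 (4.4e-07). Sprr1a and Plcxd2 were also called above the sum, but lay below background on all arrays of 2 and 3 groups, so the sizes were not measured. Trim12a lay at least 5.03 log2 units below the sum (3.12e-07) and Klk1b26 at least 3.61 (3.35e-07), as bounds with DKO arrays below background (normexp -4.06 and -2.57). Both lie on chromosome 7, so strain DNA stays open. The departure was -4.34 ± 0.63 for Esr1 (0.000253). It was -4.17 ± 0.34 for Efnb3 (2.91e-06) and -3.95 ± 0.56 for Adcy1, an adenylate cyclase (0.000221), which was well above background on 1 DKO array and had -2.16 with normexp. Calls were 3838 with slide as a block, 2704 and 188 within slides 1 and 2 and 6155 with array weights. Quantile normalization gave 1852 above and 1903 below (49.3% against 61% above).

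Of the lists, 13 departed from additivity. Cytosolic ribosomal proteins lay above the sum in 29 of 31 cases (30 adjusted over the list alone), with a median of 0.732 log2 units (slides 0.56 and 0.921, and 0.322 under quantile normalization; camera adjusted p = 7.09e-15, but adjusted p = 0.582 with an estimated correlation). Extracellular matrix and fibrosis genes did so in 19 of 37 cases (27 adjusted over the list alone), with a median of 1.13 (slides 0.705 and 1.55; 2.73e-08, adjusted p = 0.676 with an estimated correlation). Immediate early genes did so in 18 of 24 (20 adjusted over the list alone), with a median of 1.14 (slides 0.713 and 1.45; 2.7e-06, adjusted p = 0.594 with an estimated correlation). Fetal and stress genes did so in 13 of 24, with 1 below (14 adjusted over the list alone), with a median of 1.12 (slides 0.783 and 1.38; 2.22e-05, adjusted p = 0.582 with an estimated correlation). Fibroblast markers did so in 9 of 15 (9 adjusted over the list alone), with a median of 0.499 (slides 0.425 and 0.53; 0.00247, adjusted p = 0.582 with an estimated correlation). Oxidative stress genes lay above in 9 and below in 2 of 28 (13 and 2 adjusted over the list alone, median 0.457, slides 0.211 and 0.693; 0.00871, adjusted p = 0.772 with an estimated correlation). Autophagy and proteasome genes did so in 12 and 1 of 33 (13 and 1 adjusted over the list alone, median 0.268, slides 0.243 and 0.29, 0.016 under quantile normalization and 0.11 in the authors' values; 0.0104, adjusted p = 0.807 with an estimated correlation), and FoxO target genes in 10 and 1 of 29 (11 and 1 adjusted over the list alone, median 0.199, slides 0.365 and 0.185, 0.0701 under quantile normalization and 0.13 in the authors' values; 0.0115, adjusted p = 0.582 with an estimated correlation). Fatty acid oxidation genes lay below the sum in 18 of 31 cases (19 adjusted over the list alone), with a median of -0.865 (slides -0.935 and -0.648; 6.63e-10, adjusted p = 0.582 with an estimated correlation). Oxidative phosphorylation genes did so in 17 of 42 (24 adjusted over the list alone), with a median of -0.355 (slides -0.457 and -0.275, -0.673 under quantile normalization; 2e-10, adjusted p = 0.697 with an estimated correlation). Tricarboxylic acid cycle genes did so in 14 of 23 (17 adjusted over the list alone), with a median of -0.489 (slides -0.407 and -0.555, -0.925 under quantile normalization; 2.14e-09, adjusted p = 0.594 with an estimated correlation). Calcium handling and ion channel genes lay below in 17 and above in 2 of 34 (19 and 4 adjusted over the list alone, median -0.553, slides -0.596 and -0.524; 7.87e-06, adjusted p = 0.582 with an estimated correlation), and mitochondrial regulators in 5 and 1 of 22 (median -0.345, slides -0.169 and -0.387, -0.181 without DKO replicate 3; 0.0118, adjusted p = 0.772 with an estimated correlation).

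The overlap of calls was set against independent lists, which leave out the shared controls, and against simulated unchanged groups with shared controls, which leave out the effects. AKT1 KO and AKT2 KO calls shared 3 genes, Klk1b26 higher in both, Sertad3 lower in both and Kcnj14 in opposite directions. Of the 109 AKT1 KO calls 47 were called in the same direction in DKO hearts, 18 in the opposite direction and 44 were not called. The 24 shared rises and 23 shared falls compared with 13.9 and 11 from independent lists and a mean of 0.1 shared calls in 20 simulations. Of the 18 AKT2 KO calls, Akt2 included, 14 were called in the same direction and 2 in the opposite direction, with 8 shared rises and 6 shared falls against 2.44 and 1.69 from independent lists and 0.1 in the simulation. With 2 separate control arrays for each comparison 3 of 9 and 4 of 17 AKT1 KO calls and 6 of 11 and 5 of 11 AKT2 KO calls were called in the same direction in DKO hearts, and none was shared by the single knockouts. Across all genes the log2 changes of AKT1 KO and AKT2 KO correlated at r = 0.331, and those of DKO at r = 0.215 with AKT1 KO and 0.374 with AKT2 KO, where shared controls alone gave 0.399, 0.267 and 0.296 (highest 0.585, 0.425 and 0.453). The covariance with the DKO changes was 0.0341 for AKT1 KO and 0.0476 for AKT2 KO, above the highest simulated value of 0.0208, while that between the single knockouts, 0.0162, lay below its highest simulated value of 0.021. With separate controls split by slide, which may lower r, r was -0.0224 and 0.0801 between the single knockouts. It was 0.0644 and 0.158 for AKT1 KO with DKO, and 0.192 and 0.245 for AKT2 KO with DKO.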

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

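All tests of explanations in this part were chosen only after the results were seen, except the 10 Mb window around the targeted genes, and the splits of the arrays were counted after the calls had been made.

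For each knockout against control, where arrays were paired by slide and row, the 8 splits that part all 4 pairs are too few for a share under 0.05. There the real split called 109 genes in AKT1 KO, 18 in AKT2 KO and 6257 in DKO hearts and the highest other 0 in each, and the 27 splits that part fewer pairs called at most 1, 0 and 2. Between knockouts chance was excluded only over splits that exchange arrays freely across slides and rows, since 1 of 35, the real one, called as many genes. It called 6450 genes in DKO against AKT1 KO, 5780 in DKO against AKT2 KO and 123 in AKT2 KO against AKT1 KO, and the highest other split 427, 3 and 1. The 8 splits within slides and rows, of which the highest other called 0, 1 and 0, are too few for a share under 0.05. For additivity 1 of 100 splits drawn freely and 1 of 100 drawn within slides and rows, the real one with 3566, called as many. The highest other called 4 and 3470. Of the draws within slides and rows 2 left the 4 DKO arrays in 1 group, and the highest of the rest called 421. The count thus follows whether the DKO arrays stay together. These draws cannot separate a departure from additivity from a difference of DKO hearts from all others, so they do not exclude chance for it.

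Calls in the single knockouts clustered by position. In AKT2 KO hearts strain DNA linked to the floxed Akt2 allele may account for the calls near Akt2, since these were more frequent within 10 Mb than elsewhere (one-sided Fisher exact p = 1.02e-08). Loss of AKT2 as the cause of all the calls is argued against by their place, since all 18 called genes lay on chromosome 7 (Fisher exact p = 1.46e-20). By share of genes 15.6 of the 17 other than Akt2 would lie elsewhere. This covers genes with a symbol: of 8 called probes without one, 1 was annotated by a genomic interval, and it did not lie on chromosome 7. An effect of the altered allele on its neighbours stays open. In AKT1 KO hearts strain DNA linked to the floxed Akt1 allele as the whole cause is argued against, since 4.59% of the calls lay on chromosome 12. Segments of donor strain DNA elsewhere in the genome, such as on chromosome 8, may account for some calls, since called genes lay near each other more often than in random draws (permutation p = 0.005), and gene families and co-regulated neighbours stay open, as does the loss of AKT1 itself.

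The bright Esr1 probe fell by 5.33 log2 units in DKO hearts. Fewer full-length mouse Esr1 transcripts stay open. Of the 5 other probes 0 lay well above background on all 4 control arrays, but probes may differ in affinity. A lower share of cardiomyocytes is argued against by the sarcomere median of -0.318, and a fall of the Myh6 promoter output of the same size as that of Myh6 mRNA by the largest fall of a Myh6 probe, -1.73, which is smaller by 3.6 ± 0.462 (SE). A hypothesis that stays open is that the probe may read the receptor domain of the MerCreMer transgene, and that DKO hearts may carry or express less of it, but its position in the gene is not known here. A short mouse transcript also stays open.

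Matrix genes rose and genes of mitochondrial fuel use fell in DKO hearts. A lower share of cardiomyocytes as the whole cause is argued against, since markers of other cell types moved apart. The mean of fibroblast markers minus that of endothelial markers was higher by 0.405 in DKO than in control hearts, with an SD of 0.15 over the 4 pairs of arrays (0.232 to 0.595), and swaps within pairs can give no smaller exact permutation p than the 0.125 found. The scaling between arrays is argued against by the matrix median, which was 1.18 to 1.4 over 4 other scalings, with -1.35 to -1.15 for fatty acid oxidation. DKO replicate 3 alone is argued against by the matrix median of 0.977 without it. A response of the tissue to the loss of both kinases stays a hypothesis that may account for both, beside a change in the share of fibroblasts, a partial change in other cell shares and the array column, which follows the group.

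Arrays far from the other 3 of their group by the Dixon ratio were found in 28 of 354 groups of named genes with all 4 arrays well above background, 7.91% against 5% by chance, 13 of them in DKO replicate 3 and 4 in AKT1 KO replicate 1. In DKO replicate 3 the higher values, with the range of the other 3 arrays, were Bok -0.38 (-1.01 to -0.9), Des 7.04 (6.29 to 6.4), Osmr 3.1 (1.62 to 1.75), Perp 6.95 (6.08 to 6.17), Tnni2 -0.773 (-1.87 to -1.71), Tspan4 6.19 (4.54 to 4.77) and Uchl1 4.84 (3.52 to 3.6). The lower values in DKO replicate 3 were Igsf1 -1.63 (-0.479 to -0.251), Kdr 3.5 (4.11 to 4.18), Nebl 1.65 (2.06 to 2.11), Pfkm 5.15 (5.95 to 6.08), Sirt3 2 (2.9 to 2.97) and Sod2 2.15 (2.98 to 3.06). DKO replicate 4 was higher in Ankrd1 at 8.49 (8.27 to 8.31) and Myom2 at 9.25 (8.86 to 8.89). AKT1 KO replicate 1 stood apart in Akt2 at 4.51 (4.84 to 4.89), Gsta4 at 0.885 (1.27 to 1.34), Ppfibp1 at 2.79 (2.04 to 2.11) and Ptprn2 at 1.55 (1.89 to 1.9). AKT2 KO replicate 1 was lower in Adcy1 at -1.85 (-1.59 to -1.54) and Esr1 at 5.15 (5.91 to 6.02), replicate 2 higher in Gdf15 at -0.267 (-1.52 to -1.33) and replicate 3 lower in Ftl1 at 6.07 (6.24 to 6.25). Control replicate 1 was higher in Bnip3 at 5.9 (5.77 in the others) and Ndrg1 at 3.73 (3.42 to 3.44) and lower in Ppfibp1 at 0.793 (0.908 to 0.918). Control replicate 3 was lower in Alkbh6 at 2.85 (2.9 to 2.91) and Trdn at 5.06 (5.24 to 5.26).

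The DKO change differed from the sum of the single knockout changes in 3566 genes by limma. Of the named ones above background on some array of every group, Gdf15 (4.9) and Ccn2 (3.95) lay above the sum and Esr1 (-4.34), Efnb3 (-4.17) and Adcy1 (-3.95, on 1 DKO array above background) below it, in log2 units. With DKO arrays below background, Trim12a lay at least 5.03 below (fitted -6.98) and Klk1b26 at least 3.61 (fitted -5.2). Both lie on chromosome 7, so strain DNA stays open. The fitted values of Sprr1a (4.75) and Plcxd2 (4.5) are no measured sizes, since 2 and 3 of their groups lay below background.

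Probes without a gene symbol, which no comparison used, also carried a signal of the groups. Of 7056 such probes limma called 19 in AKT1 KO (10 higher, 9 lower), 8 in AKT2 KO (1 higher, 7 lower) and 2180 in DKO against control hearts (987 higher, 1193 lower).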

How the results depend on the processing

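The fits within slides, without row 2 of slide 2 and without chromosomes 7, 8 and 12 were tests chosen only after the results were seen. Over the 219 named gene results other than the 6 of Akt1 and Akt2 against control, and the alternatives chosen beforehand, other than leaving out an array, 2734 of 2784 values kept their direction and side of the threshold, 47 lost their call (22 genes) and 3 reversed. With each array left out in turn, 3412 of 3504 did so, 92 lost their call (17 genes) and 0 reversed. The 3 reversals in DKO against control hearts were Sepsecs without a filter on dim probes (-0.0303), Aqp1 under quantile normalization (-0.0963) and Acta2 with the mean of its probes (0.412); the first and last rest on other probes, and the cause of the second was not tested. AKT1 KO calls (109) became 56 without a filter, 822 with array weights, 182 with only the groups compared, 14 and 4 within slides 1 and 2, 59 without the 4 arrays of row 2 of slide 2, 46 without chromosomes 7, 8 and 12, and 54 (without control replicate 2) to 291 (without DKO replicate 3) with 1 array left out. AKT2 KO calls (18) became 93, 42, 11 and 3 with weights, only the groups compared and within slides 1 and 2, 0 by limma without chromosomes 7, 8 and 12 (314 at an unadjusted p under 0.05), and 14 (without control replicate 1) to 37 (without DKO replicate 3). The AKT2 KO against AKT1 KO calls (123) became 81 without a filter, 849 with weights, 46 and 8 within slides, 77 without row 2 of slide 2, 45 without chromosomes 7, 8 and 12, and 84 (without AKT1 KO replicate 4) to 328 (without DKO replicate 3). Within slides 1 and 2, of 8 arrays each, the DKO calls were 5648 and 2464 against control, 5997 and 2715 against AKT1 KO, 4966 and 1903 against AKT2 KO, and 2704 and 188 for additivity. With only the groups compared, DKO against AKT1 KO gave 4195, and with weights additivity gave 6155. With 1 array left out the DKO calls ranged from 5276 to 7020, those against AKT1 KO from 5660 to 7365, those against AKT2 KO from 4887 to 6514 and those for additivity from 2890 to 4808. The array weights were lowest for DKO replicate 3 (0.0608) and AKT1 KO replicate 1 (0.21). Of the 6 Akt1 and Akt2 results against control 2 crossed the threshold, with Akt1 called with weights in AKT1 KO (0.214) and under quantile normalization in DKO hearts (-0.354). The causes of these moves were not tested. Camera with an estimated correlation called 0 lists in AKT1 KO, AKT2 KO, DKO and additivity (0, 2, 4 and 3 at an unadjusted p under 0.05). Fry called 0, 0, 22 and 21 (1, 3, 24 and 22). Correlations between comparisons with 2 separate control arrays each were -0.0224 and 0.0801, 0.0644 and 0.158, and 0.192 and 0.245, lower than with shared controls (0.331, 0.215 and 0.374). Slide and row paired control with each knockout. Outside control with AKT2 KO and control with DKO the replicate numbers did not pair the arrays, since not every correlation was above 0.1 (15 of 24 were over all pairs, range -0.35 to 0.392). Of the 16 arrays 9 correlated best with their own number, and a replicate block gave 79, 17 and 6340 calls against control, 6499 and 5791 against AKT1 KO and AKT2 KO, 105 and 3493. In AKT2 KO against control hearts it ended 4 calls of named genes, given with them, and in DKO against control hearts 0, and it changed no other call of a named gene or list there. In AKT1 KO against control hearts, where the numbers did not pair the arrays, it ended the calls of Pdlim3, Helt, Ifit2, Gsta4 and Egr1, and the erythroid list was called (0.0406). Blocks for slide or for slide and row changed 0 of the list calls. Signal over background limits dim genes: 22336 of 56605 probes were well above background on all 16 arrays.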

Other observations

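The genes and probes in this part were chosen, and their tests run, only after their values were seen. In DKO hearts the myosin genes of the ventricle shifted: Myh7, the slow myosin heavy chain, rose by 2.61 log2 units from 7.01 ± 0.183 to 9.62 ± 0.24 (SD, n = 4; limma adjusted p over all kept probes = 9.91e-05), and the 2 probes of Myh6, the fast chain, fell by 0.43 and 1.73 (0.0075 and 1.84e-07). Mhrt, a noncoding RNA transcribed from the Myh7 locus, fell by 3.4, from 3.8 ± 0.0897 to 0.395 ± 0.198 (3.37e-08). In AKT1 KO and AKT2 KO hearts Myh7 spread widely, with SD of 0.639 and 0.987 and differences of 1.13 and 0.292 from control that did not pass (limma adjusted p = 0.416 and 1).

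Trim12a, which was at background in DKO hearts, fell into 2 levels among AKT2 KO hearts. Replicates 1 and 2, on slide 1, read 1.25 and 1.52 log2 units and replicates 3 and 4, on slide 2, read 0.25 and 0.183, against 1.2 to 1.36 in control hearts. A second Trim12a probe read -1.82 and -1.73 in replicates 1 and 2 and -2.68 and -2.9 in replicates 3 and 4.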
